A study of Mus musculus with 4 samples.

How the data were processed

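Bulk RNA-seq libraries of flow-sorted mouse alveolar macrophages were analysed, 2 of wild-type (WT) and 2 of osteopontin knock-out (OPNKO) mice. Per the labels, 10 stranded mRNA libraries were pooled in equal amounts and sequenced on one lane; 4 of them were analysed here. The labels mention single-cell RNA-seq in one field and bulk RNA-seq in the titles, and the values were treated as bulk. Per the submitters' processing notes, Trim Galore 0.4.0, STAR 2.4.1d, HTSeq 0.6.1p1 and edgeR were used; the notes give no role or order. The genome build, the annotation and whether counting used strand are not given in the sources used here.

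The authors deposited one table of 16755 genes. Per the file headers, it holds a normalized expression value per library, a signal obtained by dividing read counts by a size factor. The authors' log2 fold change of OPNKO over WT, its standard error, a Wald score, a p-value and an adjusted p-value stand beside it, per the file headers. The deposited adjusted p-value equals the Benjamini-Hochberg adjustment over all rows. Every value of a library was a whole multiple of the value of 1 read, so whole reads were recovered for 100% of values within a tolerance of 0.001 reads. Recovered reads summed to 41254959 and 44759630 in WT and 39980049 and 35793800 in OPNKO. The 80 rows with 0 reads in all 4 libraries carry fold changes, and the geometric mean of the 4 size factors was 0.900, so the authors' scaling and fit involved libraries beyond these 4. Another 2 columns without a label were not used. The table has 1 row with a blank symbol, which is not named.

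Groups were taken from the titles, because title and genotype tag disagree for 2 samples. The deposited values were tested with limma 3.58.1 (trend, in R 4.3.3) on log2(value + 1), OPNKO minus WT, with no covariate, among genes with a mean value of at least 1; 324 genes were left out by this filter. This replaced the edgeR quasi-likelihood test planned for raw counts, since the table holds normalized values. The added 1 shrinks the fold change of low genes, but it was not always smaller than the authors' value (Rassf6 had 5.03 here and 4.81 in their table). P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Fold changes and errors are from this test unless the authors' deposited table is named, and adjusted p-values of single genes are limma's. The median log2 fold change of all tested genes was below 0.01 in size.

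Before the data were examined, 32 gene lists were fixed. They covered alveolar macrophage programmes and markers of other cells of the lung. They were tested with camera at a preset correlation of 0.01, with its estimated correlation and with fry, adjusted over the 32 lists. With an estimated correlation, camera has only the few residual degrees of freedom of 4 libraries. A list that it did not call is therefore not shown to be unchanged. Adjustment over the list alone used the p-values of the members only. Named genes were Spp1, the 12 greatest rises and 12 greatest falls past the threshold with both libraries of one group above both of the other, and up to 4 members per list with the smallest p; predicted genes without a name were counted and not named. Genes named outside this rule were chosen after their values were seen: Car4, Cd4, Ear2, Mmp19 and Trbc1, which are list members beyond the first 4, Igha, Ighm, Cdh5, the genes near Spp1, and the genes of the closing section. Another 4 lists (thymocyte, mature T and NK cell, plasma cell and B cell genes) were added after seeing the data. Bootstrap ranges of list medians used 10000 draws over genes, which are not independent replicates. Genes within 10 Mb of Spp1 were compared with all others by Fisher's exact test. Gene positions and current symbols came from GENCODE M21 on GRCm38 by Ensembl identifier; 16542 identifiers matched and 213 did not, and 1219 symbols differ from the older ones in the table (Jchain is listed as Igj).

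Alternatives were other scaling factors, filters, pseudocounts and thresholds, each library left out in turn, the replicate number as a block, and count tests on recovered reads with edgeR 4.0.16 (694 genes by quasi-likelihood with TMM and filterByExpr) and DESeq2 1.42.0. Leaving out a library leaves its group with 1 sample, which is then assumed to vary like the other group. The limma test was tested on simulated data, with counts drawn for 16755 genes from these libraries and 200 genes changed. It recovered 64.2% of the genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold, with 14 false calls among 181. The changed genes were drawn only from those with a mean value of at least 50, so these rates do not give the sensitivity for lower genes. The rates were split by fold and not by expression level. Tables were prepared and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9.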

Results

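RNA was sequenced in bulk from alveolar macrophages, the phagocytes that reside in the air sacs of the lung, sorted by flow cytometry from the lungs of wild-type (WT) mice and of mice lacking osteopontin (OPNKO). Osteopontin is a secreted matrix glycoprotein encoded by Spp1. The samples carry a bleomycin tag (bleomycin is a drug that injures the lung and leads to fibrosis), and the deposited columns name day 14. A protocol field of the same samples speaks of no treatment. There were 2 libraries per genotype, and no untreated group was analysed here. Groups were taken from the sample titles, because the title and the genotype tag disagreed for 2 of the 4 samples. The libraries held 35793800 to 44759630 reads counted in genes. Spearman's correlation across genes was 0.992 between the libraries of each genotype, and counts differed between them by more than sampling noise, with a chi-square per degree of freedom of 15.6 between the WT libraries and 18.02 between the OPNKO libraries. The first principal component held 53.8% of the variance and separated the genotypes. The labels do not say that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333, so tests across genes came from limma, a linear model that shares the spread between genes.

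The targeted gene was measured first. Spp1 (ENSMUSG00000029304) lies on chromosome 5 from 104435118 to 104441050, plus strand, in GRCm38 with GENCODE M21. In the WT libraries it had normalized read counts of 545719 and 606517, which was 1.21% and 1.39% of all values. In the libraries titled OPNKO it had 4106 and 3847. The mean was 576118 ± 42991 (SD, n = 2) in WT and 3977 ± 183 (SD, n = 2) in OPNKO, or 0.690% of the WT level. The log2 fold change, on the log2(value + 1) scale used throughout, was -7.18 with a standard error of 0.09 (limma adjusted p = 9.12e-08). Spp1 thus followed the titles. Grouped by the genotype tag instead, the log2 fold change was 0.03. Which part of Spp1 the allele lacks is not given in the sources used here.

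The main comparison asked which genes differ between OPNKO and WT alveolar macrophages. Beyond Spp1, OPNKO libraries had lower levels of 7 of 12 MHC class II genes, of 6 of 20 monocyte markers, among them Ccr2, of the arginine-degrading enzyme gene Arg1 and of 94 of 179 immunoglobulin genes. They had higher levels of 10 of 26 genes typical of resident alveolar macrophages, such as Krt19 and Cidec, and of early T-lineage genes such as Rag1 and Dntt. The MHC class II, monocyte and resident macrophage lists passed camera at a preset correlation and did not with an estimated correlation (adjusted p = 0.542, 0.542 and 0.710). Of 16431 genes tested, 709 passed a limma adjusted p of 0.05, 383 higher and 326 lower in OPNKO, and 274 of them differed at least 2-fold (98 higher, 176 lower). The authors' deposited table held 727 genes past the same threshold, 457 higher and 270 lower, of which 537 were among the 709. The counts rest on all 4 libraries: 4 genes passed without WT replicate 1, 11 without WT replicate 2, 545 without OPNKO replicate 1 and 405 without OPNKO replicate 2. Spp1, Igha, Igkc and Jchain passed in all 4 of them.

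**Figure D1:**
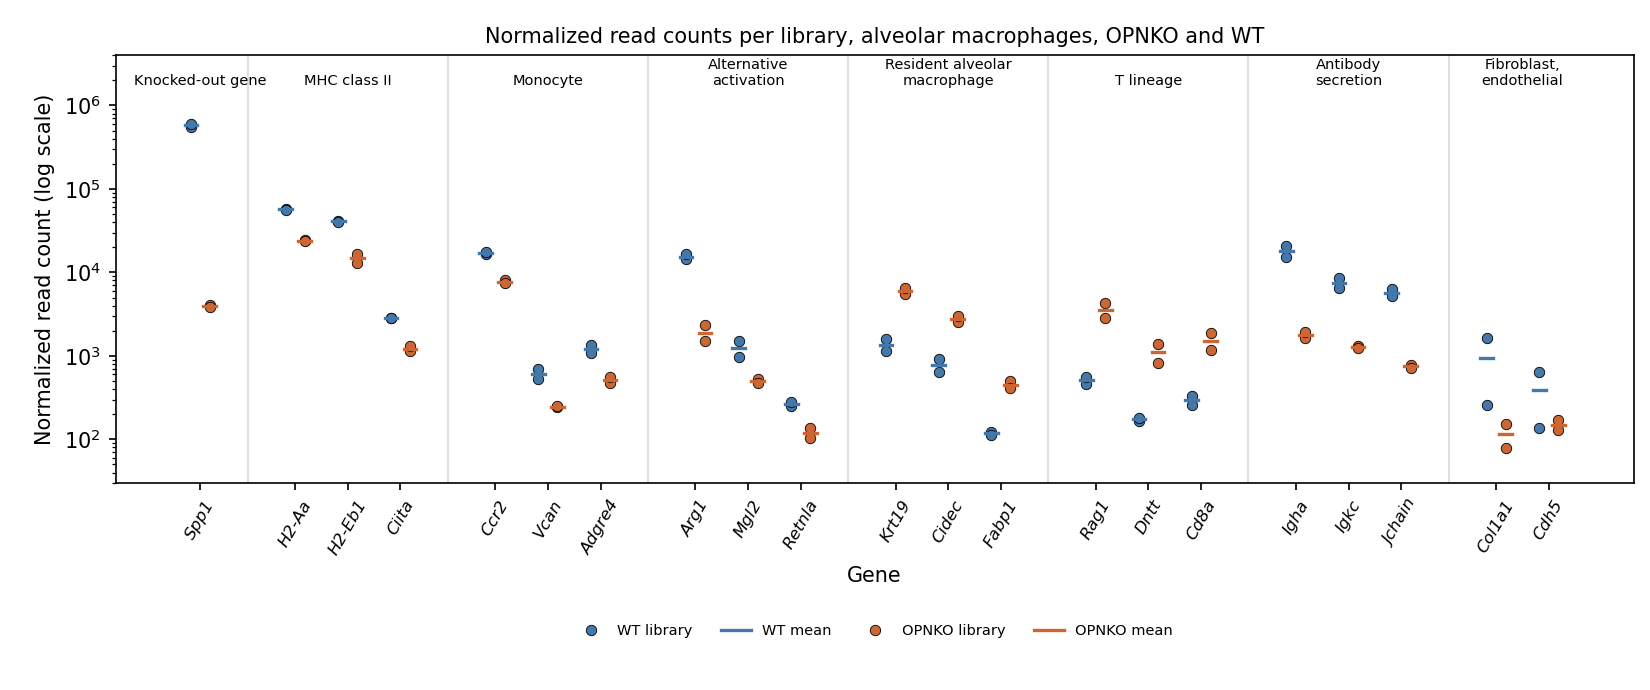
Normalized read counts (y axis, log scale) of selected genes (x axis) in the 2 WT and 2 OPNKO libraries of sorted alveolar macrophages; each point is a library and each bar the mean of its genotype. Spp1 was 576118 in WT and 3977 in OPNKO on average, and Col1a1 was 260 and 1622 in the WT libraries against 153 and 80 in the OPNKO libraries.

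The 12 rises with the greatest log2 fold change among named genes were Rassf6 (5.03), Slc10a6 (3.78), Tppp (3.51), Tdrd5 (3.08), Klc3 (3.02), Dnah11 (2.88), Chrna9 (2.82), Rag1 (2.79), Dgkeos (2.73), Arpp21 (2.66), Endou (2.65) and Dntt (2.62). Their limma adjusted p ranged from 0.00125 for Rag1 to 0.0386 for Chrna9. Rassf6 was low in WT, at 1.10 in replicate 1 and 9.76 in replicate 2 (11 reads in all). Slc10a6 (10 reads) and Klc3 (6 reads) were low in WT too, so the sizes of these rises are uncertain. Rag1, a subunit of the recombinase that assembles antigen receptor genes, went from 508 ± 65.4 to 3584 ± 1023 (SD, n = 2). Dntt, the terminal transferase that adds nucleotides during this assembly, went from 174 ± 8.30 to 1107 ± 400 (SD, n = 2). Dgkeos is named as an antisense transcript of Dgke, and its value is uncertain because the sources used here do not state whether counting used strand. Of the 12 greatest falls, Spp1 was 1 and 11 were immunoglobulin variable segments, with log2 fold changes from -5.87 (Igkv14-100) to -4.64 (Igkv9-124). Variable segments are near-identical copies among which reads can be split, so single segments are uncertain. Both Igkv12-38 and Ighv9-4 had 0 reads in both OPNKO libraries. Against a floor of 3 reads over the group, Igkv12-38 was at least 19.7-fold lower and Ighv9-4 at least 24.98-fold lower in OPNKO. Floors cover counting error only, and Ighv9-4 differed between the WT libraries (65.8 and 23.4), so its bound depends on the library.

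MHC class II genes, which present antigen to CD4 T cells, were lower in OPNKO. Of 12 tested, 7 fell and 0 rose (8 fell when adjusted over the list alone). H2-Aa fell from 56765 ± 1598 to 23960 ± 703 (SD, n = 2), a log2 fold change of -1.24 ± 0.07 (SE; limma adjusted p = 8.49e-04). Ciita, the transactivator of these genes, fell by 1.22 on the log2 scale, H2-Eb1 by 1.47 and the invariant chain gene Cd74 by 1.07. The list ranked lower than other genes by camera (adjusted p = 5.87e-08 at a preset correlation of 0.01), which was lost at an adjusted p of 0.542 with an estimated correlation. Markers of dendritic cells, which also carry MHC class II, were lower beside it. Of 14 tested, 2 fell, Fscn1 (-1.94) and Mgl2 (-1.27), or 5 when adjusted over the list alone, and the median was -0.34 with a 95% bootstrap range of -0.92 to -0.18 (camera adjusted p = 0.00301, and adjusted p = 0.710 with an estimated correlation). These markers also differed between the WT libraries, with a median 0.34 higher in WT replicate 2 (10 of 14 higher).

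Among 20 markers of monocytes and monocyte-derived macrophages, 6 fell and 0 rose (6 and 1 when adjusted over the list alone). Ccr2, the receptor that draws monocytes into tissue, fell from 17093 ± 353 to 7775 ± 337 (SD, n = 2; log2 fold change -1.14, limma adjusted p = 7.92e-04). Ace fell by 0.77, Adgre4 by 1.23 and Vcan by 1.30 on the log2 scale. The list's median was -0.19, with a 95% bootstrap range of -0.34 to -0.08 (camera adjusted p = 1.73e-04, and adjusted p = 0.542 with an estimated correlation). Of 17 genes of alternative activation, the macrophage state linked to type 2 cytokines, 6 fell and 0 rose (10 and 0 when adjusted over the list alone). Arg1 fell from 15384 ± 1421 to 1901 ± 583 (SD, n = 2; log2 fold change -3.05, limma adjusted p = 9.00e-04), and the lectin genes Mgl2 (-1.27) and Clec10a (-1.39) and the secreted protein gene Retnla (-1.14) fell with it. Mgl2 is also a dendritic cell marker, and the dendritic cell markers (12 of 14 negative) and the complement and interstitial macrophage markers (11 of 15 negative) both had a median of -0.34. For this list camera gave an adjusted p of 2.50e-06, and an adjusted p of 0.542 with an estimated correlation.

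Of 26 genes of resident alveolar macrophage identity, 10 rose and 2 fell (10 and 3 when adjusted over the list alone). Krt19, a keratin, rose from 1364 ± 332 to 5974 ± 730 (SD, n = 2; log2 fold change 2.15, limma adjusted p = 0.00161). The lipid-handling genes Fabp1 (1.93) and Cidec (1.85) and the adhesion gene Cd2 (1.71) also rose. Pparg, which encodes the nuclear receptor that drives the alveolar macrophage programme, rose by 0.41, while Car4 (-0.68) and Ear2 (-0.39) fell. The list ranked higher than other genes by camera (adjusted p = 7.85e-05), with an adjusted p of 0.710 with an estimated correlation. Of 29 genes of lipid uptake, storage and efflux, 5 rose and 1 fell (8 and 1 when adjusted over the list alone). The cholesterol exporter gene Abcg1 rose by 0.58, and the scavenger receptor gene Msr1 fell by 0.38 on the log2 scale (camera adjusted p = 0.00111, and adjusted p = 0.710 with an estimated correlation). Of 23 genes of cholesterol biosynthesis, 3 rose and 0 fell (11 and 0 when adjusted over the list alone). These were Idi1 (0.48), Sc5d (0.42) and Cyp51 (0.39), with a camera adjusted p of 4.12e-06 for the list and an adjusted p of 0.710 with an estimated correlation. All 23 were also lower in WT replicate 2 than in WT replicate 1, by a median of 0.18 on the log2 scale. In the authors' deposited table Cyp51 passed (Wald test, adjusted p = 0.00490), while Idi1 (adjusted p = 0.169) and Sc5d (adjusted p = 0.0553) did not.

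The 24 fibrosis-associated macrophage genes, a list that includes Spp1 itself, did not move one way. Spp1 and Arg1 fell, while Gpnmb, a glycoprotein gene of lipid-laden macrophages, rose by 0.57, the growth factor gene Igf1 by 0.39 and the matrix protease gene Mmp19 by 0.63. When adjusted over the list alone, 5 rose and 3 fell. The median of the list was 0.03, its mean -0.39 and its camera direction lower (adjusted p = 0.971). Of 11 osteopontin receptor genes (integrins and Cd44), the integrin gene Itga9 fell (-1.67, limma adjusted p = 0.0376), and 1 rose and 1 fell when adjusted over the list alone. Cd44 had a log2 fold change of 0.41 (limma adjusted p = 0.0782). In the authors' deposited table Itga9 did not pass (Wald test, adjusted p = 0.0540) and Cd44 did (adjusted p = 1.42e-04). The median was -0.02 and the mean -0.18, with a camera direction of higher (adjusted p = 0.868).

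Among 24 inflammatory cytokines and chemokines, Ccl3 (0.76) and Tnf (0.79) rose, and Ccl17 (-2.02) and Cxcl9 (-1.69) fell; 2 rose and 3 fell when adjusted over the list alone. The list had a camera adjusted p of 0.303, and 0.00518 without OPNKO replicate 1. Of 28 type I interferon response genes, Ifi47 fell (-0.53), also when adjusted over the list alone (camera adjusted p = 0.246). Of 23 TGF-beta and growth factor signalling genes, Tgfb2 (1.51) and Igf1 rose and Areg, which encodes the epidermal growth factor receptor ligand amphiregulin, fell from 561 ± 84.3 to 77.7 ± 8.12 (SD, n = 2; log2 fold change -2.83, limma adjusted p = 0.00109). When adjusted over the list alone, 3 rose and 1 fell (camera adjusted p = 0.295, and 0.00862 without OPNKO replicate 1). Of 24 matrix and matrix-remodelling genes, 2 rose and 5 fell (5 and 9 when adjusted over the list alone). Thbs1 (-1.66), Vcan and Mmp9 (-1.56) fell and Mmp8 (0.67) rose. The camera adjusted p was 0.0364, and it was 0.0764 without WT replicate 2, 0.205 without OPNKO replicate 2 and 0.754 with an estimated correlation. WT replicate 2 carried more fibroblast transcripts than WT replicate 1, by a median of 2.03 on the log2 scale over 15 markers.

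Of 23 glycolysis and hypoxia genes, the glucose transporter gene Slc2a1 fell (-0.43) and the regulatory enzyme gene Pfkfb3 rose (0.43); 12 fell and 1 rose when adjusted over the list alone. Camera gave an adjusted p of 4.74e-05 and, with an estimated correlation, an adjusted p of 0.542. This was the 1 list of 32 called by fry, which tests whether genes move one way on balance (adjusted p = 0.0193). Of 32 nuclear-encoded oxidative phosphorylation genes, 0 passed in either direction by limma, also when adjusted over the list alone; 11 fell at an unadjusted p under 0.05, and 0 fell by edgeR's quasi-likelihood test and 1 by DESeq2. Their median was -0.16 (camera adjusted p = 5.51e-04, and adjusted p = 0.710 with an estimated correlation). Of 33 cell cycle genes, Mcm5 (-0.53) and Ccne2 (-0.56), both of DNA replication, fell (7 fell and 1 rose when adjusted over the list alone). Of the 33, 31 were higher in OPNKO replicate 2 than in OPNKO replicate 1, by a median of 0.26 on the log2 scale, and the camera adjusted p of 0.00111 became 0.969 without OPNKO replicate 1, and adjusted p was 0.754 with an estimated correlation. Of 30 lysosome and phagocytosis genes, the inhibitory antibody receptor gene Fcgr2b fell (-0.89), and 3 rose and 1 fell when adjusted over the list alone. The median was 0.07 and the mean -0.01, and the camera adjusted p of 0.0975 (higher) became 0.0362 without WT replicate 1 and 0.0307 without OPNKO replicate 2. Of 20 NRF2 antioxidant genes, Hmox1, the haem-degrading enzyme gene, fell (-0.77), and 1 rose and 2 fell when adjusted over the list alone. The camera adjusted p was 0.0520; it was 0.0153 without WT replicate 2, 0.0253 with the replicate block, 0.0445 and 0.0448 with other scaling factors, and 0.0459 among genes of mean value 50 or more. Of 18 unfolded protein response genes, 0 passed by limma, also when adjusted over the list alone, and 0 at an unadjusted p under 0.05, by edgeR or by DESeq2 (camera adjusted p = 0.542). Of 24 immediate-early and heat-shock genes, which dissociation can induce, Hsph1 rose (0.37), also when adjusted over the list alone. Their median was 0.01 and their mean -0.08 (camera adjusted p = 0.938). Without OPNKO replicate 1 the list was lower (adjusted p = 0.0126), and without OPNKO replicate 2 it was higher (adjusted p = 0.00185).

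**Figure D2:**
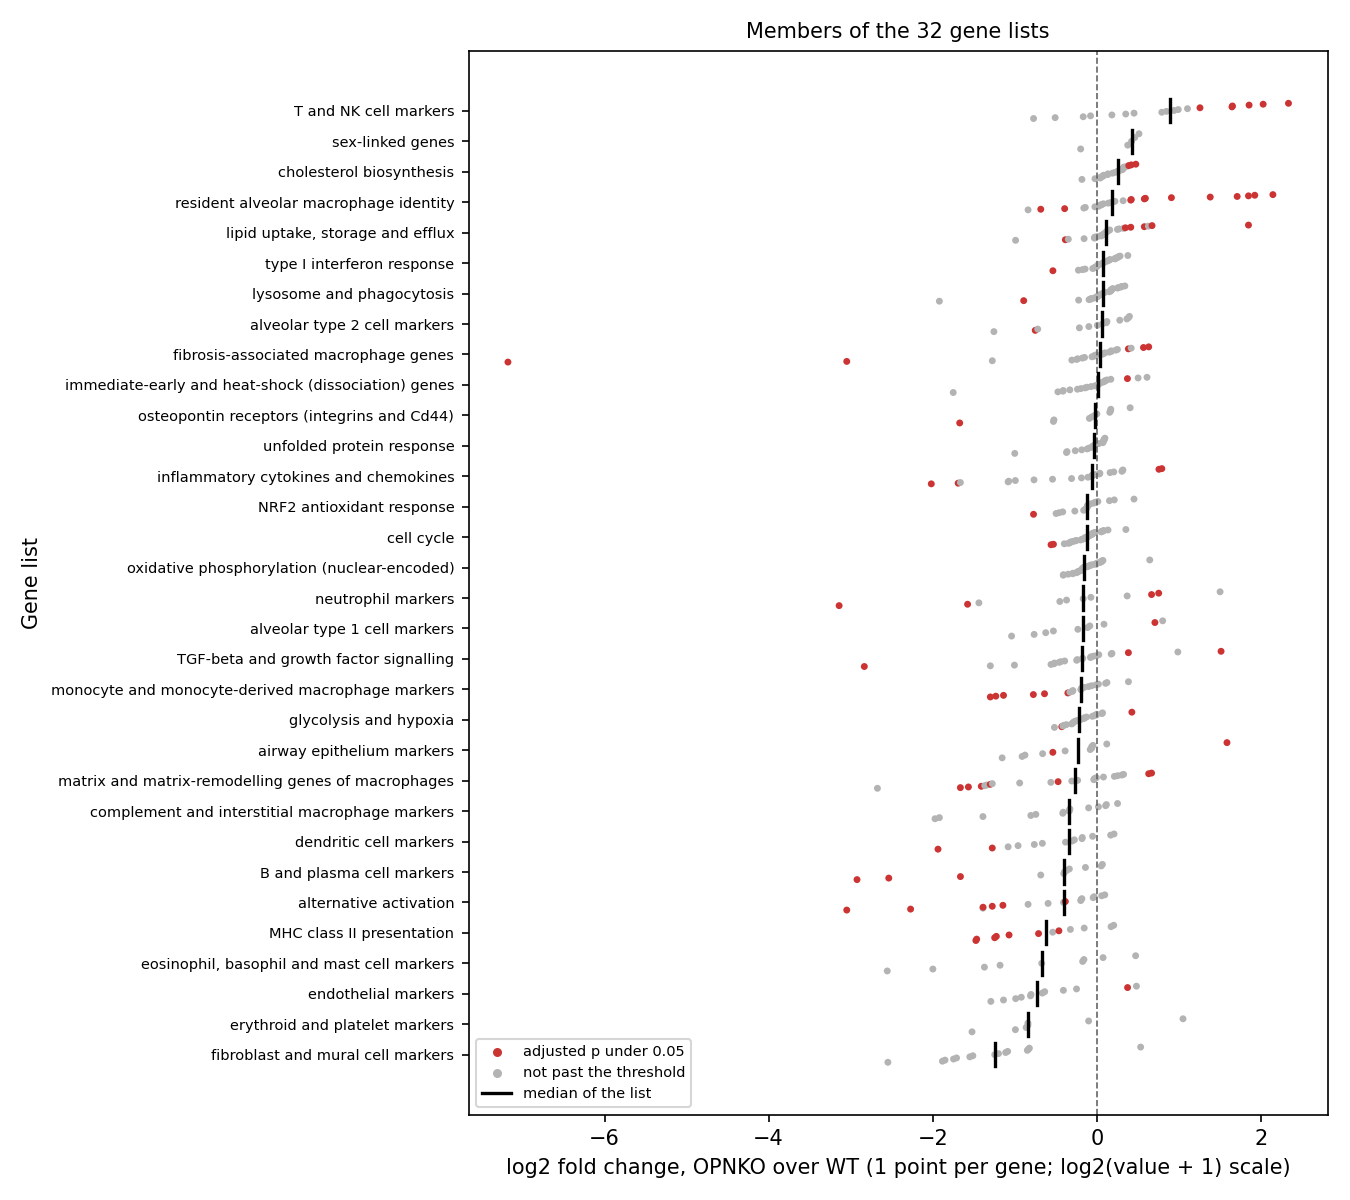
Log2 fold changes of OPNKO over WT (x axis, log2(value + 1) scale) of the tested members of 32 gene lists (y axis), 1 point per gene; red points passed a limma adjusted p of 0.05, grey points did not, and black bars are list medians. The MHC class II median was -0.62, the resident alveolar macrophage median 0.18 and the T and NK cell median 0.90.

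Some markers of lymphocytes moved with genotype. Of 18 T and NK cell markers, 6 rose and 0 fell (10 and 0 when adjusted over the list alone). Cd8a rose from 296 ± 54.4 to 1527 ± 489 (SD, n = 2; log2 fold change 2.34, limma adjusted p = 0.00364). Cd8b1 (2.03), the kinase gene Lck (1.65), Trbc2 (1.86), Trbc1 (1.65) and Cd4 (1.26) rose as well. These genes differed between the OPNKO libraries too, with a median 0.79 higher in OPNKO replicate 2 on the log2 scale. The camera adjusted p was 6.88e-06, and adjusted p was 0.710 with an estimated correlation. Of 11 B and plasma cell markers, 3 fell and 0 rose, with the same counts when adjusted over the list alone. They were Jchain, the joining chain of secreted IgA and IgM (-2.92, limma adjusted p = 7.73e-05), Igkc (-2.54) and Mzb1 (-1.66), with a camera adjusted p of 1.02e-04 for the list and an adjusted p of 0.710 with an estimated correlation. All 11 were higher in WT replicate 2 than in WT replicate 1, by a median of 0.43, and the list's median fold change was -0.39, both on the log2 scale. Of 179 annotated immunoglobulin genes tested, a set chosen after the values were seen, 94 fell and 0 rose, and 176 had a negative log2 fold change. Their median was -2.94, and it was also -2.94 with the 11 genes at 0 reads in OPNKO set to the floor. Immunoglobulin genes made up 0.0943% and 0.131% of the values in WT and 0.0211% and 0.0207% in OPNKO. Igha, the IgA heavy chain, fell from 18042 ± 3634 to 1801 ± 200 (SD, n = 2; log2 fold change -3.31, limma adjusted p = 2.07e-04). Ighm, the IgM heavy chain, had a log2 fold change of -0.37 (limma adjusted p = 0.373). Without immunoglobulin genes and the lymphoid lists, an alternative chosen after seeing the data, 557 genes passed and 212 of them were lower.

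Markers of stromal and blood cells set WT replicate 2 apart. All 15 fibroblast and mural cell markers were higher in WT replicate 2 than in WT replicate 1, by a median of 2.03 on the log2 scale, and Col1a1 was 1622 against 260. All 12 endothelial markers were also higher there, by a median of 2.02, and Cdh5 was 639 against 135. The medians for erythroid and platelet markers (1.85) and alveolar type 2 cell markers (1.63) pointed the same way. Of the fibroblast list 0 genes passed by limma, also when adjusted over the list alone, and 6 fell at an unadjusted p under 0.05. The list had 0 falls by edgeR's quasi-likelihood test, 6 by its exact test and 1 by DESeq2. Its median was -1.24 (camera adjusted p = 3.19e-04, 0.0591 without WT replicate 2, and adjusted p = 0.754 with an estimated correlation). Of the endothelial list Vwf rose (0.38), or 2 genes when adjusted over the list alone, with a median of -0.73 (camera adjusted p = 0.416). Without WT replicate 1 the endothelial list was lower (adjusted p = 5.79e-05), and without WT replicate 2 it was higher (adjusted p = 0.0372). Of 13 alveolar type 2 markers Napsa fell (-0.75), and 1 rose and 1 fell when adjusted over the list alone; the median was 0.07 and the mean -0.10 (camera adjusted p = 0.696). Without WT replicate 1 this list was lower (adjusted p = 0.00139), and without WT replicate 2 higher (adjusted p = 0.0251). Of 10 alveolar type 1 markers Cav1 rose (0.71), and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.618). Of 12 airway epithelium markers Tppp3 rose (1.59) and Cdh1 fell (-0.54), also when adjusted over the list alone (camera adjusted p = 0.334, and 0.0269 without WT replicate 1).

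Of 11 neutrophil markers, Mmp8 (0.67) and the chemokine receptor gene Cxcr2 (0.75) rose and Retnlg (-3.14) and the decoy receptor gene Il1r2 (-1.57) fell, also when adjusted over the list alone (camera adjusted p = 0.870). Of 9 eosinophil, basophil and mast cell markers 0 passed by limma, and 2 fell when adjusted over the list alone. At an unadjusted p under 0.05, 2 fell. Of these markers 0 fell by edgeR's quasi-likelihood test, 2 by its exact test and 1 by DESeq2. The eosinophil chemokine receptor gene Ccr3 had a log2 fold change of -2.00 (limma adjusted p = 0.0560). The camera adjusted p of 0.0856 was 0.0363 without WT replicate 1 and 0.0307 without OPNKO replicate 2. Of 7 erythroid and platelet markers 0 passed by limma, also when adjusted over the list alone; 1 rose at an unadjusted p under 0.05, and 0 by edgeR or DESeq2 (camera adjusted p = 0.359). Of 15 complement and interstitial macrophage markers 0 passed by limma, and 1 rose and 5 fell when adjusted over the list alone. At an unadjusted p under 0.05, 1 rose and 6 fell. Of these markers 0 fell by edgeR's quasi-likelihood test, 4 by its exact test and 3 by DESeq2. Their median was -0.34, and it was 0.55 lower in OPNKO replicate 2 than in OPNKO replicate 1, with a camera adjusted p of 0.00964 that became 0.0965 without WT replicate 2 and 0.387 without OPNKO replicate 2, and adjusted p was 0.754 with an estimated correlation. In all, camera called 16 of 32 lists at the preset correlation and 0 with an estimated correlation (1 at an unadjusted p under 0.05), and fry called 1. The glycolysis and hypoxia list had an estimated correlation of -0.04, below the preset 0.01, and was lost as well. Correlation between genes thus does not explain the loss of this list, and with few residual degrees of freedom the test had little power. Estimated correlations of the 16 called lists ran from -0.04 to 0.98 (sex-linked genes). For lists estimated above 0.01, such as cholesterol biosynthesis (0.65) and fibroblast and mural cell markers (0.89), the p-values at the preset correlation may be too small.

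The knocked-out allele can carry linked sequence of the strain in which it was made, so genes near Spp1 on chromosome 5 were counted. Within 10 Mb of Spp1, 6 of 152 tested genes passed (3.95%), against 4.31% of the genes elsewhere, an odds ratio of 0.912 with a 95% interval of 0.328 to 2.04 (two-sided Fisher's exact test, p = 1). Within 5 Mb, 5 of 76 passed, with an odds ratio of 1.57. The nearest genes that passed were Pkd2 (0.54), Aff1 (0.53) and Slc10a6 (3.78), all higher in OPNKO and within 1 Mb. Slc10a6 had 10 reads in WT in all, so the size of its rise is uncertain. In this 1 Mb window, chosen after these values were seen, 3 of 17 genes passed, with an odds ratio of 4.77 and a 95% interval of 0.878 to 17.2 (two-sided Fisher's exact test, p = 0.0345). Both greatest rises of named genes lie within 20 Mb of Spp1, Rassf6 at 13.8 Mb and Slc10a6 at 0.83 Mb, as do the falls of Areg at 13.3 Mb and of Jchain at 15.9 Mb. With calls limited to changes of at least 2-fold, an alternative chosen after these values were seen, 11 of 346 genes passed within 20 Mb (5 higher, 6 lower; odds ratio 1.98, 95% interval 0.968 to 3.65, two-sided Fisher's exact test, p = 0.0503) and 3 of 152 within 10 Mb (odds ratio 1.19).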

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

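The settings without a plan before the data were examined included the 1 Mb window and the removal of lymphoid genes. Also unplanned were the fibrosis list without Spp1, TMM factors in limma and, for the genes near Spp1, all settings but the other windows. The edgeR quasi-likelihood test with TMM factors had been planned as the main test for raw counts. It was run here as an alternative on recovered reads. The count of 709 genes (383 higher, 326 lower) stayed within 1.5 times under other scaling factors, filters and pseudocount, edgeR's quasi-likelihood test, limma-voom and the authors' table (578 to 768 genes). DESeq2 on recovered reads gave 1136 (620 higher, 516 lower) and edgeR's exact test 1611 (852 and 759). A threshold of 1.5-fold gave 422 (185 higher), an adjusted p under 0.01 gave 161 (81 and 80), and lower genes numbered 212 without lymphoid genes. Leaving out a library gave 4 to 545 genes, 0 to 213 higher and 4 to 332 lower. Each of these fits has 3 libraries and 1 lone group, so this does not explain why they called 4 and 11 genes without a WT library and 545 and 405 without an OPNKO library. The cause was not tested, nor for DESeq2 and the exact test. Same-numbered samples did not deviate together across genes (correlation -0.02). With 2 libraries per genotype this cannot exclude that same-numbered samples share an origin. With the replicate block, limma gave 1566 genes (875 and 691) and edgeR 1719 (903 and 816). Grouping by the genotype tag gave 0 genes by limma (0 higher, 0 lower; 230 at an unadjusted p under 0.05), 0 by edgeR and a Spp1 log2 fold change of 0.029; it sets the libraries numbered 1 against those numbered 2. Spp1 stayed between -7.25 and -7.10 with a library left out. The 16 lists called by camera became 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 1 by fry. With 4 libraries the test with an estimated correlation has little power, so its result does not show that the lists are unchanged.

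The odds ratio near Spp1 (0.912) lay above 1 in the windows of 5 Mb (1.57), 20 Mb (1.22) and 1 Mb (4.77), for calls of at least 2-fold within 10 Mb (1.19) and 20 Mb (1.98), without immunoglobulin and lymphoid genes (1.16), with no filter (1.01), pseudocount 0.1 (1.08), edgeR without a filter (1.00), voom (1.15) and the authors' table (1.07). With a library left out it ran from 0 to 1.36. Fisher's exact p was 0.0345 in the 1 Mb window and 0.0503 for the calls of at least 2-fold within 20 Mb. Calls of at least 2-fold within 1 Mb and 5 Mb also lay above 1, with Fisher's exact p of 0.248 and 0.361. In the other settings above 1 this p was 0.384 or more, and the cause was not tested. With a library left out, the log2 fold changes of 5 uncalled genes crossed 0: Lcn2 from -2.52 to 0.0087, Emp2 from -1.31 to 0.064, Hbb-bt from -2.08 to 0.091 and Ddx3y from -0.017 to 0.77, each with its change of sign without WT replicate 2, and Ppbp from -1.76 to 0.082, without OPNKO replicate 2. So did 3 lists, with camera adjusted p from 0.00185 to 0.685 for immediate-early genes (0.0126, reversed, without OPNKO replicate 1), from 0.00139 to 0.907 for alveolar type 2 markers (0.0251, reversed, without WT replicate 2) and from 5.79e-05 to 0.778 for endothelial markers (0.0372, reversed, without WT replicate 2). Medians of alveolar type 2 and endothelial markers were 1.63 and 2.02 higher in WT replicate 2 than in WT replicate 1 on the log2 scale; the cause was not tested. Among the other alternatives of named genes, 2400 kept direction and side of the threshold, 232 lost the call and 169 gained one; of lists, 358 kept it, 40 lost it and 15 gained one. At 35793800 to 44759630 reads per library and 2 libraries per group, simulated changes were called in 64.2% of genes at 1.5-fold, 88.1% at 2-fold and 98.5% at 4-fold. The rates hold for the genes changed in the simulation. Those genes all had a mean value of at least 50, so sensitivity for lower genes is not known from the rates. They were also not split by expression level.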

Other observations

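Of the tests below, that of near-identical variable segments, the use of mature T and NK cell genes as a control for the thymocyte genes, the use of the T and NK cell markers beside them, that of reads failing to align, that of the 1 Mb window and those of calls of at least 2-fold near Spp1 and of plasma cell genes without Jchain were chosen after the result was seen, as were the 4 lists of thymocyte, mature T and NK cell, plasma cell and B cell genes.

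Outside immunoglobulins, the greatest falls in OPNKO were a mixed group. They are named after their values were seen, and each passed limma's adjusted p of 0.05. The adhesion molecule gene Vcam1 went from 739 ± 111 to 143 ± 22.4 (SD, n = 2; log2 fold change -2.36, limma adjusted p = 0.00145). Stbd1, which encodes a glycogen-binding protein, had a log2 fold change of -3.32, the lipoxygenase gene Alox15 -2.30, the macrophage secreted protein gene Cd5l -2.37 and the calcium channel gene Cacna1h -2.40. Mucl1 (-2.51) and Slc16a9 (-2.27) fell too. Ankrd1 had 0 reads in OPNKO and was at least 8.57-fold lower against a floor of 3 reads over the group. In the authors' deposited table Cacna1h, Mucl1 and Ankrd1 did not pass (Wald test, adjusted p = 0.406, 0.0629 and 0.0546), while the others named here did. Of 5 sex-linked genes tested, 0 passed by limma, and 2 rose when adjusted over the list alone; 2 rose at an unadjusted p under 0.05, 0 by edgeR's quasi-likelihood test and 1 by DESeq2. Xist had 1 to 2 reads in each library, and the Y-linked gene Ddx3y was at 6248 and 3618 in WT and at 6475 and 5889 in OPNKO. The list's camera adjusted p of 0.0394 was 0.228 without WT replicate 2, 0.0799 without OPNKO replicate 1 and 0.0583 without OPNKO replicate 2, and adjusted p was 0.754 with an estimated correlation.

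Genes of immature thymocytes, and some of the wider T lineage (6 of 18 T and NK cell markers), were higher in OPNKO. The 20 thymocyte genes, of which 14 rose and 0 fell, had a median log2 fold change of 2.02 (95% bootstrap range 1.43 to 2.25). Mature T and NK cells cannot be told apart from other sources. A set of 21 of their genes had a median of -0.43 (-0.51 to -0.08), below a bound of 1.01 for excluding them. This bound was taken from the thymocyte median of these data, and both lists were chosen after the data were seen. The set of 21 also left out T cell genes shared with thymocytes that rose. The 18 T and NK cell markers fixed before the data were examined had a median of 0.90 (0.27 to 1.38). Thymocytes carried into the sort cannot be told apart either. Their genes also differed between the OPNKO libraries, by a median of 0.66 (18 of 20 higher in OPNKO replicate 2). This lay outside the 95% range of random lists matched on expression, -0.11 to 0.10, as was predicted for thymocytes carried over. But the mature T and NK cell genes differed too, by 0.47 (16 of 21), outside their range of -0.24 to 0.18. The T and NK cell markers differed by 0.79, so this difference does not point to thymocytes. Rag1 reached 3584 and Satb1 2275 in OPNKO, but Ptcra, another thymocyte gene, was at 10.9 against 4.27 in WT (limma adjusted p = 0.440). A sort on macrophage surface markers should remove such cells. Transcripts typical of other cells were present all the same, such as Col1a1 at 1622 in WT replicate 2. A biological difference between the genotypes, in these cells or in macrophages, stays open and was not tested.

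Immunoglobulin genes were lower in OPNKO. Reads split between near-identical variable segments are argued against as the whole cause: of 9 constant-region genes tested, which are counted apart from these segments, 4 fell and 0 rose. Igha (-3.31) and Igkc (-2.54) were among those that fell, and Ighm (-0.37, limma adjusted p = 0.373) did not pass. Fewer plasma cells, or less of their RNA, in the OPNKO libraries may account for it. The 14 plasma cell genes other than immunoglobulins, of which 5 fell and 9 did not pass, had a median of -0.39 (-0.85 to -0.13). Jchain was at 5745 in WT and 754 in OPNKO. The immunoglobulin genes fell further, with a median of -2.94, so whether this accounts for the whole of their fall is not shown. Jchain lies 15.9 Mb from Spp1, so linked sequence could also bear on it; the other 13 had a median of -0.30 (-0.72 to -0.13). Whether B cells of every kind were fewer cannot be told apart from this, because 16 B cell genes, of which 1 rose and 0 fell, had a median of -0.19 (-0.40 to 0.07) and some of them, such as Cd22 at 8209 in WT, were also high in these macrophage libraries. Macrophage sorting should remove both cell types, but Igha was still at 18042 in WT. An effect of genotype on these cells stays open, untested.

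Linked donor-strain sequence was a hypothesis set before the data were examined, and whether it adds differing genes near Spp1 cannot be told apart from chance. The odds ratio within 10 Mb was 0.912 with a 95% interval of 0.328 to 2.04, and it was 1.57 within 5 Mb and 1.22 within 20 Mb. A lower 95% bound below 1 and a share of called genes at most 1.5 times that elsewhere had been set beforehand as evidence against it. Both were met, but the interval reaches 2.04, so an excess is not excluded. Several of the largest changes lie further out, such as Rassf6 (5.03), Stbd1 (-3.32), Areg (-2.83) and Jchain (-2.92) at 11.8 to 15.9 Mb, and calls of at least 2-fold within 20 Mb had an odds ratio of 1.98 (0.968 to 3.65), an interval that reaches below 1. Reads of such sequence failing to align are argued against as the source of most calls within 10 Mb, since 83.3% of the 6 genes that passed there were higher in OPNKO. An effect of the targeted allele on the genes next to it stays open: within 1 Mb the odds ratio was 4.77, with an interval that reaches below 1, and the window was chosen because of the genes in it.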
